A study of Mus musculus with 6 samples.

How the data were processed

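RNA from inguinal white adipose tissue was measured on 6 Affymetrix arrays, 1 per mouse, from 3 wild-type (WT) and 3 Atf7 knockout (KO) male mice aged 5 weeks. Groups and replicate numbers came from the sample titles, and the series description gives the replicates of both groups as mice. The deposited table holds 1 log2 expression value per probe set and array, for 34760 probe sets. RMA, affy and limma were named for these values, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarizes probes into a log2 value. Tool versions, the options used and the genome build of the array annotation were not given in the sources used here. A scale in log2 was also checked on the values, which ran from 1.44 to 14.15 with array medians from 6.41 to 6.49. Because quantile normalization gives arrays nearly the same distribution, a shift shared by most genes would not be visible in these values. The number of arrays, 3 per group, limits the precision.

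Probe sets were named from the platform annotation table. Of the 34760 probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 had no listed gene. Symbols were compared through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, where 19855 of 19937 genes matched and 0 symbols had to be updated. The same table gave the order of neighbouring genes and nothing else. A gene was represented by its probe set with the highest mean over all 6 arrays, which applied to 954 genes with several probe sets. Probe sets with several symbols or none were left out of the gene tests and were used only in the fit over all probe sets.

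Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, KO against WT, two-sided) on the log2 values as deposited, with no filter on dim genes and no fold cut. P-values were adjusted by the Benjamini-Hochberg method over 19937 genes, with a threshold of 0.05 on the adjusted p. The Atf7 probe sets were tested in a fit over all probe sets. Standard errors (SE) are limma's moderated ones. With 3 arrays against 3, an exact permutation test of a single value cannot go below 0.1.

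Gene lists were tested with camera, a limma test of whether the genes of a list rank higher or lower than all other genes, with the preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 43 lists. The lists held 1266 entries, of which 1150 were measured, and a list needed at least 5 measured genes. They covered adipocyte, thermogenic, lipid, mitochondrial, interferon, stress and clock programmes, and markers of other cells that a dissected inguinal depot can hold. A list's level on an array is the mean of its genes after each gene was centred on its mean over the 6 arrays. The lymphocyte score is that mean over the B cell and T cell lists together, and the muscle score is that of the skeletal muscle list. Fry, a limma test of whether a list's genes move one way without reference to other genes, was run beside camera, as was camera with a correlation estimated per list.

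Genes next to Atf7 were the 50 measured genes on each side in chromosome order, or fewer where the chromosome ended. Their share at an unadjusted p under 0.01 was compared with that of all other genes with a place by Fisher's exact test, two-sided. This threshold applied because fewer genes than the rule required passed the adjusted one.

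The genes named in the text followed a fixed rule. It took Atf7, the genes past the threshold with no overlap between groups or, if these were few, the 10 genes with the smallest p in each direction, a fixed set of 12 adipocyte and thermogenic genes and related regulators, up to 4 genes with the smallest p of each list described, and the genes next to Atf7 that passed that test. Predicted genes, olfactory and vomeronasal receptors and antigen receptor segments were skipped among the smallest p. Of the fixed set, 11 genes were analysed here, and 1 was not analysed here. Groups, tests, lists, naming rule and all alternatives but 1 were set before the data were examined. Genes singled out on other grounds are said to have been chosen after their values were seen.

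The gene test was tested on simulated data for KO against WT, 19937 genes with 200 changed, in 20 draws with variances drawn from the fitted prior. It recovered 78.5% of log2 changes of 1, 97.4% of changes of 2 and 99.5% of changes of 3, with 5.36% false calls. All draws had independent genes and the same noise on all 6 arrays. In the real data KO replicate 3 stood apart, so these rates need not hold for it. Camera recovered 60 of 60 lists shifted by 0.3 on the log2 scale and called 1 of 639 unshifted lists, with genes simulated as independent. The test of neighbouring genes called 20 of 20 draws with 20 neighbours changed by 2 on the log2 scale, and 0 draws without. These draws do not show whether it can find fewer or smaller changes.

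The alternatives were other normalizations between arrays, a filter on dim genes, the mean of all probe sets of a gene, other variance models, array weights, the replicate number as a block, the lymphocyte or muscle score as a covariate, each array left out in turn, other thresholds, other list tests and other neighbourhood widths. Figures were drawn with matplotlib 3.10.9.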

Results

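Gene expression was profiled in inguinal white adipose tissue, a subcutaneous fat depot that can acquire heat-producing beige adipocytes. The arrays came from 3 KO mice lacking the transcription factor Atf7 and 3 WT littermates, all males of the C57BL/6 strain aged 5 weeks. The comparison asks, as the series title states it, how Atf7 bears on fat cell differentiation and on thermogenic genes. Replicates are mice per the series description, so the spread is between animals. Correlations between arrays ran from 0.984 to 0.990 among the 5 arrays other than KO replicate 3, and from 0.969 to 0.981 for KO replicate 3 with the others, across probe sets. Along the first principal component, which held 56.4% of the variance, KO replicate 3 lay at 50.25, KO replicate 1 at 8.98, KO replicate 2 at -12.94 and the WT arrays between -17.66 and -13.97. Lymphocyte markers differed in the same arrays. The lymphocyte score was -2.30 in KO replicate 3, -0.10 in KO replicate 1, 0.57 in KO replicate 2 and 0.48 to 0.72 in the WT arrays.

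Atf7, a basic leucine zipper transcription factor of the ATF/CREB family and the targeted gene, was represented by 2 probe sets. Probe set 10433032 fell by 2.66 on the log2 scale (SE 0.12), from 9.07 ± 0.12 in WT to 6.41 ± 0.17 in KO (SD, n = 3), which is 6.32-fold lower, with an adjusted p of 0.00658 from limma over all probe sets. It was 6.22, 6.53 and 6.49 in the KO arrays and 8.95, 9.20 and 9.07 in the WT arrays, so every KO array lay below every WT array, as its label requires. Probe set 10433034 was 9.25 ± 0.16 in KO and 9.42 ± 0.09 in WT, a log2 difference of -0.17 with an adjusted p of 0.730. The part of the gene that the allele removes was not given in the sources used here, and a probe set outside it checks nothing. Probe set 10433034 has the higher mean and represented Atf7 in the gene fit, where the gene did not pass (adjusted p 0.657). The adjusted p of probe set 10433032 was 0.0745 without WT replicate 1 and 0.147 without WT replicate 3. It was 0.0792 with the replicate number as a block and 0.108 with the lymphocyte score as a covariate.

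Of the 10 genes with the smallest p among those higher in KO, 3 belonged to the thermogenic list, and none of the 10 passed adjustment over all genes. Ucp1, the uncoupling protein that lets mitochondria produce heat, was 7.49-fold higher, at 9.26 ± 0.45 in KO and 6.35 ± 0.60 in WT (SD, n = 3), a log2 difference of 2.91 (SE 0.33). Cox7a1, a cytochrome c oxidase subunit of heart, muscle and brown fat, was 2.85-fold higher (log2 1.51, SE 0.17). The lipid droplet protein gene Cidea was higher by 1.59 on the log2 scale (SE 0.24), at 10.47 ± 0.30 in KO and 8.89 ± 0.42 in WT. For these 3 genes every KO array lay above every WT array, and limma's adjusted p was 0.237 for Ucp1 and Cox7a1 and 0.487 for Cidea.

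Limma called 0 genes higher and 0 lower at an adjusted p under 0.05, with 0.237 as the smallest adjusted p. At an unadjusted p under 0.05 there were 1489 genes, 995 higher and 494 lower in KO, where 997 are expected by chance. That number was 758 without KO replicate 1 (560 higher, 198 lower), 789 without WT replicate 3 (597 and 192) and 3757 without KO replicate 2 (2068 and 1689), while 619 were higher without KO replicate 3 and 251 lower without WT replicate 1. It was 777 with the lymphocyte score as a covariate (455 and 322), 970 with the muscle score (653 and 317), 1495 with arrays shifted to a common median (1114 and 381), 2944 with gene-by-gene array weights (1615 and 1329) and 7413 with default ones (3668 and 3745), so the excess of higher genes differed with these choices. The same test over all probe sets called 0 higher and 2 lower, the mean of all probe sets per gene gave 0 higher and 1 lower, and default array weights, which did not converge, gave 1688 higher and 1432 lower. Groups did not overlap for 13.9% of genes, where chance gives 10%, with KO above for 1587 and below for 1190.

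The other 7 genes with the smallest p among those higher in KO did not pass adjustment over all genes either. Ntrk3, the receptor for neurotrophin 3, was 2.58-fold higher (log2 1.37, SE 0.14). Phospho1, a phosphatase of phosphocholine and phosphoethanolamine, was 2.62-fold higher (log2 1.39), and Me3, mitochondrial malic enzyme, was 1.91-fold higher (log2 0.93). Itih4, an inter-alpha-trypsin inhibitor heavy chain, was 3.91-fold higher, Impdh1, an enzyme of guanine nucleotide synthesis, 1.95-fold, Tspan4 1.63-fold and Zfp524 1.47-fold. Their adjusted p-values from limma lay between 0.237 and 0.487. The genes with the smallest p among those lower in KO differed less. They were Npff, a neuropeptide gene (log2 -0.51), the translation factor subunit Eif3f (-0.39), Prr9 (-0.49), the cornified envelope gene Sprr2e (-0.43), the meiotic gene Spo11 (-0.55), Podnl1 (-0.37), Zfp746 (-0.37), Pou3f2 (-0.46), the interleukin 12 subunit Il12a (-0.65) and the transcription factor Foxo1 (-0.37). All 10 had an adjusted p of 0.622. In each of them every KO array lay below every WT array, which choice by smallest p favours. Prr9, Sprr2e, Spo11, Podnl1, Pou3f2 and Il12a were dimmer than the median gene, as was Me3 among the higher genes. Spo11 was at 4.36 in KO and 4.91 in WT, and Sprr2e at 4.53 and 4.95.

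Of the 11 fixed adipocyte and thermogenic genes analysed here, 0 passed over all genes and 3 passed when adjusted over the list alone, namely Ucp1 (0.000523), Cidea (0.00134) and Ppargc1a (0.0324). Over the list alone Ucp1 and Cidea passed without each array in turn, while Ppargc1a was at 0.0563 without WT replicate 1, 0.0600 without WT replicate 2, 0.138 without WT replicate 3 and 0.0605 without KO replicate 1. Ppargc1a, a coactivator that drives mitochondrial biogenesis, was 1.82-fold higher in KO (log2 0.86, SE 0.24), and its difference was 0.46 with the lymphocyte score as a covariate. Prdm16, a coregulator of brown and beige fat identity, differed by 0.24 (SE 0.16), with the groups overlapping. Its difference was 0.13 without KO replicate 3 and 0.40 without KO replicate 2, where it passed over the list alone, and 0.055 with the lymphocyte score as a covariate. The adipogenic transcription factors Pparg, Cebpa and Cebpb differed by 0.40, 0.27 and 0.35, with standard errors of 0.20, 0.19 and 0.21, and none passed over all genes. Without WT replicate 3 these differences were 0.25, 0.08 and 0.16. Without WT replicate 2 Pparg was at 0.61 and passed over the list alone, Cebpa and Pparg were at 0.14 and 0.27 without KO replicate 3, and Cebpb was at 0.19 without KO replicate 1. The 4 products of mature fat cells in the fixed set were close in both groups. Fabp4, a fatty acid carrier, was 12.69 ± 0.08 in KO and 12.61 ± 0.04 in WT, and the adipokine Adipoq 12.46 ± 0.22 and 12.47 ± 0.09. The adipokines Lep and Retn differed by 0.15 and -0.09, from -0.06 to 0.35 and from -0.16 to -0.01 without each array in turn, and these 4 genes had adjusted p-values between 0.772 and 0.987.

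**Figure D1:**
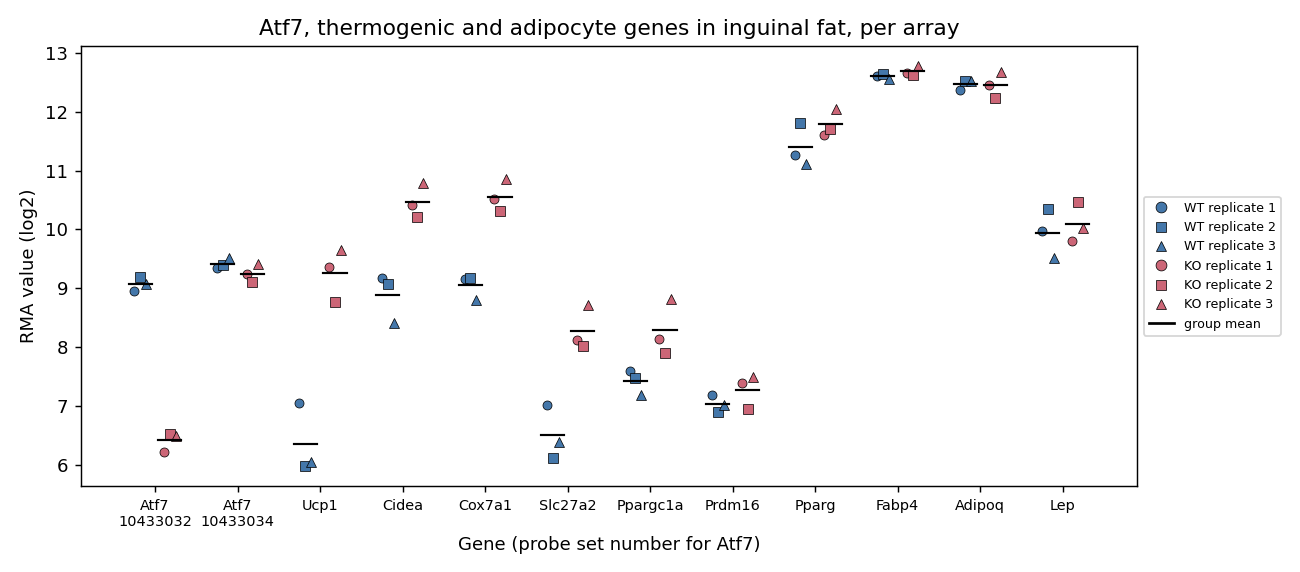
RMA values (log2 scale) of the 2 Atf7 probe sets and of 10 thermogenic and adipocyte genes, 1 point per array, 3 arrays per group, with lines at the group means. In Ucp1, Cidea, Cox7a1, Slc27a2 and Ppargc1a the 3 KO arrays lie above the 3 WT arrays, in Atf7 probe set 10433032 they lie below, and in Fabp4, Adipoq and Lep the groups overlap.

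Of the 43 gene lists, camera with the preset correlation called 24 at an adjusted p under 0.05, 14 higher and 10 lower in KO. None of the 24 calls held with an estimated correlation, where the smallest adjusted p of all lists was 0.592 and the largest among these 24 was 0.782. Fry called 0 lists, with 0.165, for the thermogenic list, as its smallest adjusted p. Without KO replicate 3 the number of lists called lower was 6. In level, all KO arrays lay above all WT arrays in 6 of the 43 lists and below in 1. Chance gives such a separation for 10% of single values. The lymphocyte score is made from the B cell and T cell lists, so using it as a covariate does not test these 2. Of the other 22 lists called, 11 kept their direction and call with it, and the calls of the lists of adipogenic transcription factors, lipolysis, endothelial, brown depot, interferon-gamma, JAK-STAT, dendritic, lymph node stromal, ribosomal, cell cycle and skeletal muscle genes ended or turned. No gene of any list passed over all genes, so members are counted by sign, by unadjusted p and by adjustment over the list alone.

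The thermogenic and beige adipocyte list rose. Of 33 measured genes, 28 were positive and 18 were higher at an unadjusted p under 0.05, with 0 lower. Of these, 16 were higher when adjusted over the list alone. The median log2 difference was 0.46, with an adjusted p of 3.29e-14 by camera (adjusted p = 0.592 with an estimated correlation). The list's level was 0.26, 0.18 and 0.44 in the KO arrays and -0.18, -0.30 and -0.41 in the WT arrays, with an exact permutation p of 0.1, the smallest that 3 against 3 can give. Slc27a2, a fatty acid transport protein and acyl-CoA synthetase, was 3.41-fold higher in KO (log2 1.77, SE 0.27). KO replicate 3, with the lowest lymphocyte score (-2.30), had the highest level of the list, while KO replicate 2, with a score inside the WT range (0.57), was also above all WT arrays. Zic1 and Lhx8, transcription factors used as markers of the classical brown depot and chosen for a test before their values were seen, differed by 0.00 and -0.09 (95% intervals -0.23 to 0.24 and -0.46 to 0.29).

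Lists of mitochondrial fuel use rose alongside. In fatty acid oxidation 23 of 25 genes were positive, 15 were higher at an unadjusted p under 0.05 and 15 when adjusted over the list alone, with a median of 0.49 and an adjusted p of 1.01e-12. Over the list alone 3 genes passed without WT replicate 3, 2 without KO replicate 1 and 5 without KO replicate 3. Acaa2 and Hadhb, which cleave fatty acids in the mitochondrial spiral, were 1.91-fold and 1.66-fold higher, Acadvl, which starts that spiral, 1.65-fold, and Ppara, a nuclear receptor that induces it, 2.54-fold. In oxidative phosphorylation 45 of 47 genes were positive and 27 were higher at an unadjusted p under 0.05, with 0 when adjusted over the list alone, a median of 0.36 and an adjusted p of 2.57e-17. The 27 became 8 without WT replicate 1, 7 without WT replicate 3, 14 without KO replicate 1 and 10 without KO replicate 3, and without KO replicate 2, 33 passed over the list alone. Its members included Cox6b1 (log2 0.55), Atp5o (0.45), Uqcrc1 (0.53) and Sdhb (0.51), subunits of the respiratory chain complexes and ATP synthase. In the citric acid cycle 21 of 22 genes were positive, 11 were higher at an unadjusted p under 0.05 and 4 when adjusted over the list alone, with a median of 0.36 and an adjusted p of 2e-10. The 11 became 7 without WT replicate 1, 4 without WT replicate 3 and 7 without KO replicate 3, and over the list alone 2 passed without WT replicate 3, 8 without WT replicate 2 and 14 without KO replicate 2. Idh2, Suclg1 and Sucla2 were 1.45-fold, 1.59-fold and 1.83-fold higher. Each of these 3 lists had an adjusted p of 0.592 with an estimated correlation. In KO these levels ran opposite to the lymphocyte score. KO replicate 3 was the highest array in all 3 lists (0.42 to 0.52) and KO replicate 2 lay between -0.02 and 0.03. In oxidative phosphorylation and the citric acid cycle KO replicate 2 was at about the level of WT replicate 2 (-0.02). In fatty acid oxidation all WT arrays lay lower (-0.43 to -0.14). With the lymphocyte score as a covariate the medians were 0.26, 0.18 and 0.18, still past camera's threshold (adjusted p 8.13e-09, 2.4e-09 and 1.46e-05), and without KO replicate 3 the oxidative phosphorylation median was 0.24.

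Lists of lipid synthesis, lipolysis and adipocyte regulation also rose, by smaller amounts. Of their measured genes, 7 of 15 in lipolysis and 12 of 26 adipogenic transcription factors are also in other lists. Each of these 2 lists shares 1 gene with the thermogenic list, Cidea and Ebf2 respectively. The lipolysis list's entries include genes that drive lipid release, such as Pnpla2, and genes that restrain it, such as G0s2. Its rise therefore gives no direction of release. De novo lipogenesis had 21 of 25 genes positive, 6 higher at an unadjusted p under 0.05 and 0 when adjusted over the list alone (median 0.20, adjusted p 4.93e-05, and adjusted p = 0.592 with an estimated correlation). Elovl6, which elongates fatty acids, was 1.54-fold higher, and Acacb, an acetyl-CoA carboxylase, 1.45-fold. The median was 0.35 without WT replicate 2 and 0.09 without WT replicate 3, and both calls stayed. The 6 became 12 without WT replicate 2, and over the list alone 8 genes passed without that array and 3 without KO replicate 2. Lipolysis had 14 of 15 genes positive and 1, Cidea, past when adjusted over the list alone (median 0.18, adjusted p 0.00221, and adjusted p = 0.592 with an estimated correlation), but 0.0674, with a median of 0.07, without KO replicate 3, and a median of 0.30 without KO replicate 2. Adipogenic transcription factors had 22 of 26 positive and 0 past over the list alone (median 0.14, adjusted p 0.0101, and adjusted p = 0.592 with an estimated correlation), but 0.136 without WT replicate 3, and had a median of 0.07 without that array and without KO replicate 3, and 1 gene passed over the list alone without KO replicate 2. Among them, Ebf2, a factor of beige and brown precursors, was 1.57-fold higher. Mature white adipocyte genes did not pass (19 of 27 positive, median 0.09, adjusted p 0.269), with differences of 0.43 for Trarg1 and -0.65 for Adig. Neither did cholesterol synthesis and uptake (0.0844), glycolysis (0.109), insulin signalling (0.351) or repressors of adipogenesis (0.697). Within that last list 17 of 29 genes were positive, among them Twist2 (log2 0.48) and Hes1 (0.20). In the other direction Gata3, a zinc finger factor of precursors and T cells, differed by -1.01 (SE 0.35), and by -0.65 without WT replicate 2.

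The circadian clock list rose, with 17 of 20 genes positive, 6 higher at an unadjusted p under 0.05 and 1 when adjusted over the list alone. Its median was 0.29 and its adjusted p 0.000858 (adjusted p = 0.592 with an estimated correlation). The clock output gene Dbp was 1.74-fold higher, the repressor Nr1d2 1.36-fold and Cry2 1.31-fold. All 3 KO arrays (0.06 to 0.22) lay above the WT arrays (-0.29 to -0.01), and the median without WT replicate 3 was 0.18. The 6 became 3 without WT replicate 1 and without WT replicate 3, and over the list alone 0 to 3 genes passed without each array in turn, 0 for 4 of the 6 arrays. The hour of dissection was not given in the sources used here.

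Lymphocyte genes fell, most of all in KO replicate 3. All 26 T cell genes were negative, 4 of them at an unadjusted p under 0.05 and 0 past when adjusted over the list alone, with a median of -1.21 and an adjusted p of 1.28e-12. Of 23 B cell genes 22 were negative, 0 at an unadjusted p under 0.05, with a median of -1.30 and an adjusted p of 7.78e-08. The T cell genes Bcl11b, Cd27, Skap1 and Zap70 differed by -0.88, -1.49, -1.12 and -0.88, and the B cell factor Pax5 by -1.39 with an SD of 1.70 in KO. Without KO replicate 3 these 5 genes differed by -0.60, -0.76, -0.55, -0.43 and -0.44. The T cell list lay at -1.99 in KO replicate 3, -0.25 in KO replicate 1, 0.51 in KO replicate 2 and 0.48 to 0.67 in WT. Without KO replicate 3 the medians were -0.44 for T cells and -0.33 for B cells, and the B cell median was -1.95 without KO replicate 2. The 4 T cell genes became 26 without KO replicate 2, 8 without KO replicate 3, 0 without WT replicate 3 and 1 without each of the other arrays. Without KO replicate 2 all 26 T cell genes and 21 B cell genes passed over the list alone, and without each of the other arrays 0 did. At an unadjusted p under 0.05 there were 21 B cell genes without KO replicate 2 and 0 without each of the others. Both lists had an adjusted p of 0.592 with an estimated correlation.

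Other immune lists fell in the same arrays. Lymph node stromal and high endothelial genes (13 of 15 negative, median -0.42, adjusted p 0.000399) had a median of -0.19 without KO replicate 3. Glycam1, a mucin of lymph node venules, stood at 8.94 ± 3.23 in KO and 12.01 ± 0.33 in WT, a difference of -3.07, which was -1.23 without KO replicate 3 (adjusted p 0.622 with all arrays). Dendritic cell genes (16 of 21 negative, median -0.37, adjusted p 0.000574) had medians of -0.12 without KO replicate 3, -0.58 without KO replicate 2 and -0.57 without WT replicate 2. Genes of the interferon-gamma response and antigen presentation (26 of 34 negative, median -0.13, adjusted p 0.000564) had medians of -0.08 without KO replicate 3 and -0.22 without KO replicate 2. Irf8, a factor of dendritic and B cells, differed by -0.90, and by -0.47 without KO replicate 3, and Tap1, a peptide transporter, by -0.38, and by -0.23 without that array. JAK-STAT pathway genes (18 of 26 negative, median -0.11, adjusted p 0.0220) were at 0.295 (median -0.04) without KO replicate 3 and 0.117 without WT replicate 2, and had a median of -0.17 without KO replicate 2. That call also ended with default array weights (0.160), gene-by-gene weights (0.0780) and the muscle score as a covariate (0.0715). Each of these 4 lists had 0 genes past when adjusted over the list alone and an adjusted p of 0.592 with an estimated correlation. Without KO replicate 2, 6 lymph node genes passed lower over the list alone, and 10 dendritic cell genes passed lower and 1 higher. Type I interferon-stimulated genes did not pass (27 of 40 negative, median -0.05, adjusted p 0.0580), nor did inflammatory cytokines and NF-kB targets (0.204), macrophage (0.565), natural killer (0.776), plasma cell (0.535) or neutrophil and mast cell genes (0.697).

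**Figure D2:**
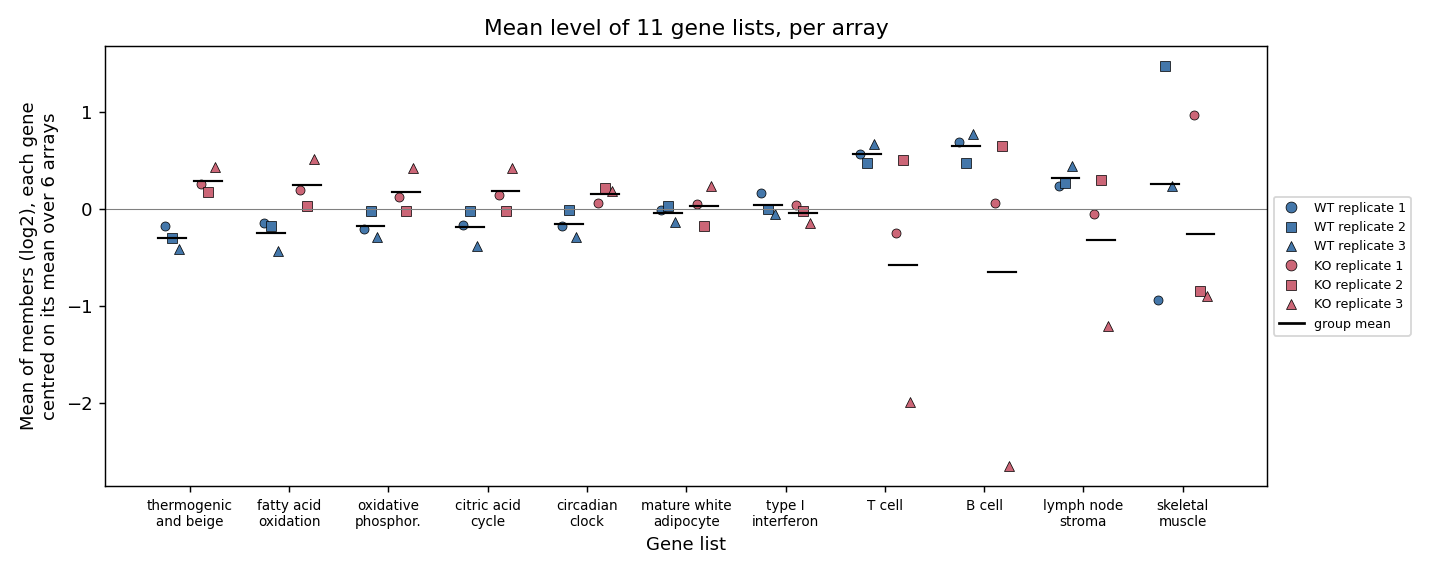
Mean level of 11 gene lists on each array (log2 scale, each gene centred on its mean over the 6 arrays), 3 arrays per group, with lines at the group means. The thermogenic list separates the groups (0.18 to 0.44 in KO, -0.41 to -0.18 in WT). So do fatty acid oxidation (0.03 to 0.52 and -0.43 to -0.14), the circadian clock and, barely, oxidative phosphorylation. The T cell, B cell and lymph node lists are lowest in KO replicate 3 and at WT levels in KO replicate 2.

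Among lists of vessel, stroma and other cells, mural and smooth muscle genes rose (19 of 21 positive, median 0.20, adjusted p 0.000232), with Cspg4 1.51-fold and Rgs5 1.46-fold higher, both pericyte genes. The median was 0.33 without KO replicate 2. Endothelial and lymphatic vessel genes (22 of 28 positive, median 0.18, adjusted p 0.00908) were at 0.0943 without KO replicate 1 and had a median of 0.10 without KO replicate 3. Extracellular matrix genes (36 of 44 positive, median 0.12, adjusted p 0.00488) were at 0.486 (median 0.05) without KO replicate 1 and had a median of 0.20 without KO replicate 2. Adipocyte progenitor genes (24 of 29 positive, median 0.22, adjusted p 0.00987) were at 0.196 (median 0.14) without KO replicate 1, 0.0659 without WT replicate 1 and 0.0534 without WT replicate 2. Their median was 0.37 without KO replicate 2, 0.15 without KO replicate 3 and 0.34 without WT replicate 3. Schwann cell and neuronal genes (16 of 22 positive, median 0.17, adjusted p 0.0136) were at 0.157 without KO replicate 2, 0.0599 without WT replicate 1 and 0.0534 (median 0.10) without WT replicate 2, and at 0.248 among genes at or above the median level. Brown depot and muscle-lineage genes (16 of 23 positive, median 0.24, adjusted p 0.00825) were at 0.131 (median 0.15) without KO replicate 3 and had medians of 0.14 without WT replicate 2 and 0.15 without WT replicate 3, and were at 0.160 with default array weights and 0.0572 with gene-by-gene ones. With an estimated correlation these 6 lists had an adjusted p of 0.592, except 0.626 for extracellular matrix, and 0 of their genes passed when adjusted over the list alone. Without KO replicate 2 this became 2 for progenitor genes (1 higher, 1 lower) and 1 for Schwann cell genes, without WT replicate 1 it became 1 for mural genes, and without WT replicate 2 it became 2 for brown depot genes.

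Ribosomal protein genes fell (37 of 44 negative, median -0.15, adjusted p 5.79e-05, and adjusted p = 0.638 with an estimated correlation), but were at 0.443 (median -0.01) without KO replicate 3 and had a median of -0.24 without KO replicate 2. Cell cycle genes fell (29 of 45 negative, median -0.05, adjusted p 0.0223, and adjusted p = 0.625 with an estimated correlation), but were at 0.496 (median -0.01) without KO replicate 3 and 0.0561 without WT replicate 3, and had a median of -0.08 without KO replicate 2. That call also ended with the arrays quantile-normalized again (0.0695), with default array weights (0.148) and with gene-by-gene weights (0.0803). Skeletal muscle genes (31 of 38 negative, median -0.55, adjusted p 0.0320, and adjusted p = 0.782 with an estimated correlation) had a median of 0.01 without WT replicate 2 (19 of 38 negative) and an adjusted p of 0.560 without KO replicate 2 and 0.754 without KO replicate 3. Their median was -1.11 without KO replicate 1, -1.10 without WT replicate 1, -0.28 without KO replicate 2 and -0.21 without KO replicate 3, and turned to 1.08 with default array weights and 0.44 with gene-by-gene ones. The list's smallest p belonged to Cox8b, a cytochrome c oxidase subunit shared with brown fat, which was 1.74-fold higher. Epithelial and mammary gland genes (21 of 25 negative, median -0.31, adjusted p 0.00102, and adjusted p = 0.592 with an estimated correlation) were at 0.326 (median -0.05) without WT replicate 2 and had a median of -0.48 without WT replicate 3. In these 4 lists 0 genes passed when adjusted over the list alone, and without KO replicate 2 1 ribosomal and 1 cell cycle gene did. No call was made for keratinocyte (0.261), erythrocyte (0.868), immediate early (0.347), heat shock (0.206), hypoxia (0.159), unfolded protein response (0.697), ATF, CREB and AP-1 family (0.858) or glucocorticoid-responsive genes (0.861). Median and mean differed in sign for the ATF, CREB and AP-1 family (-0.01 and 0.02), neutrophil and mast cell (0.03 and -0.01), natural killer (0.07 and -0.04) and erythrocyte genes (0.01 and -0.01).

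Genes next to Atf7 were examined because a knockout allele can carry linked DNA or affect its neighbours. Npff, the measured gene beside Atf7 on one side, was 1.43-fold lower in KO (log2 -0.51, SE 0.09), and Hoxc5, a homeobox gene at place 12 on the other side, was 1.48-fold higher (log2 0.57, SE 0.11). These 2 of 79 neighbours (2.53%) had an unadjusted p under 0.01, against 227 of 19775 other genes (1.15%). The odds ratio was 2.24 (95% interval 0.265 to 8.45), with p = 0.231 by Fisher's exact test. Without KO replicate 3 the share was 5.06% against 0.829% elsewhere (Fisher's exact p = 0.00454), and without KO replicate 2 it was 5.06% against 5.67% elsewhere (Fisher's exact p = 1). At an unadjusted p under 0.05 the share was 7.59% against 7.46% (Fisher's exact p = 0.832). Many neighbours on the side of Npff were keratin genes, which were dim. On the side of Hoxc5, Glycam1, the lymph node gene described above, lay at place 28 (log2 -3.07, unadjusted p from limma 0.0647).

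**Figure D3:**
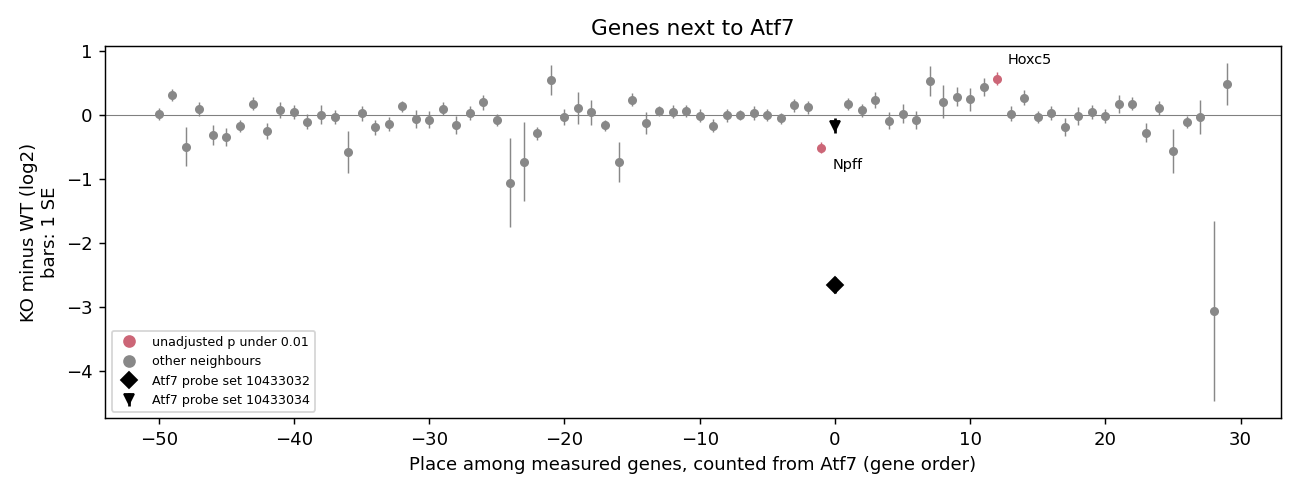
Log2 difference of KO minus WT (bars, 1 SE of limma) for the measured genes around Atf7, by place in chromosome order, with both Atf7 probe sets at 0. Npff (-0.51) and Hoxc5 (0.57) are the neighbours with an unadjusted p under 0.01.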

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

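Array weights fitted gene by gene were added after the data were seen, because the default weights did not converge (KO replicate 1 had a weight of 13.43). Genes called higher stayed at 0 under all alternatives except default array weights, with 1688 higher and 1432 lower; gene-by-gene weights gave 0 and 0. Genes called lower were 2 over all probe sets and 1 with the mean of all probe sets, Atf7. Lists called were 0 higher and 0 lower with an estimated correlation and with fry, and with the lymphocyte score as a covariate 2 were lower, 1 of them the T cell list; without each array in turn, 11 to 17 were higher and 6 to 11 lower, the 6 without KO replicate 3. Of the 22 lists called outside the lymphocyte score, 7 kept direction and call under all 17 other alternatives; the B and T cell lists make up that score, which does not test them, and both kept theirs under the other 16. The skeletal muscle median turned to 1.08 with array weights, 0.444 with gene-by-gene weights, and ran from -1.108 to 0.014 without each array in turn, the latter without WT replicate 2. With the lymphocyte score as a covariate, medians turned to 0.071 for B cell (not a test), 0.041 for lymph node stromal, 0.035 for ribosomal and 0.001 for cell cycle genes; the causes were not tested. Atf7 probe set 10433032 stayed between -2.78 and -2.56 throughout, and between -2.72 and -2.56 without each array in turn; with the lymphocyte score it was -2.69 with an adjusted p of 0.108. The range of its adjusted p over alternatives was 0.00117 to 0.147. Among genes at or above the median level, the share changed next to Atf7 was 6.06% of 66 neighbours, against 1.29% elsewhere (Fisher's exact p = 0.0113). These neighbours were counted anew among such genes, so they are not the same set as the 79 of the main test. Without each array in turn the share was 2.53% to 5.06%. At 5.06% without KO replicate 2 it lay below the 5.67% elsewhere (odds ratio 0.887, Fisher's exact p = 1).

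Same-numbered KO and WT arrays did not deviate together (r across genes -0.143, -0.079 and -0.045). These values cannot tell whether the replicate numbers pair the mice, with 3 arrays per group and KO replicate 3 standing apart. With the number as a block, limma called 0 genes, 14 lists were higher and 10 lower (skeletal muscle genes were lost, at 0.0624, and type I interferon-stimulated genes gained, at 0.0488), Atf7 probe set 10433032 was -2.66 with an adjusted p of 0.0792, and the share next to Atf7 was 3.8% (Fisher's exact p = 0.0451). Of 3831 results under alternatives, 54 changed the direction of their test with neither setting past its threshold. For lists this direction can differ from the sign of the median. Low signal limits genes near the floor of the arrays.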

Other observations

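The tests on lymphoid cells and lymph node tissue, and the count of splits for genes past the adjusted threshold, were chosen only after the results they bear on were seen. The probe sets and genes of the next paragraph were also chosen after their values were seen.

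Fabp3, a fatty acid carrier of heart, muscle and brown fat, had 2 probe sets that disagreed. Probe set 10508614 was 8.75-fold higher in KO, at 9.74 ± 0.41 against 6.62 ± 0.58 in WT (SD, n = 3), with an adjusted p of 0.227 from limma over all probe sets. Probe set 10371502 was 9.49 ± 0.34 and 9.11 ± 0.39. An unnamed probe set, 10341037, was the only one besides Atf7 past the threshold, at 2.22 ± 0.07 in KO and 4.73 ± 0.30 in WT (adjusted p 0.0261). Both means lay below the lower quartile of every array (5.05 to 5.14), so its signal was low. Of the 9 Hoxc genes measured near Atf7, 7 had a positive difference, among them Hoxc6 (log2 0.43) and Hoxc10 (0.53). Skeletal muscle genes varied within both groups, at 1.48, 0.24 and -0.94 in WT and 0.97, -0.85 and -0.90 in KO, without order. Epithelial and mammary gland genes stood at 0.80 in WT replicate 2 and between -0.23 and -0.12 in the other 5 arrays. Pdk4, which restrains glucose oxidation, was 2.59-fold higher in KO, and P2rx5, a purinergic receptor of brown fat, 1.81-fold (log2 0.85, and 0.52 without WT replicate 3), with an adjusted p of 0.622 each.

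If the higher thermogenic genes in KO came only from a lower share of lymphoid cells, thermogenic and white adipocyte genes would move together. Their difference within each array was 0.20 to 0.36 in KO and -0.33 to -0.17 in WT, a shift of 0.518. KO replicate 2, with lymphocyte genes at the WT level, was above all WT arrays in the thermogenic list. These values were compared after both lists had been seen, so they are no independent test of dilution. With the lymphocyte score as a covariate the thermogenic median was 0.37 (0.46 without it). Ucp1 was then at 2.59 (2.91 without it), Ppargc1a at 0.46 (0.86) and Prdm16 at 0.055 (0.24). Tissue of the classical brown depot would raise Zic1 and Lhx8, and the higher upper end of their 95% intervals was 0.289, under the bound of 1 set beforehand. Because both genes were dim (4.99 and 6.36 in KO, with the median gene at 6.89), that bound could miss a small share of such tissue, and the brown depot and muscle-lineage list was higher in KO (median 0.24, adjusted p 0.00825), a call that ended with an estimated correlation (0.592), without KO replicate 3 (0.131), with the lymphocyte score as a covariate (median 0.09, adjusted p 0.419) and with array weights (0.160 by default, 0.0572 gene by gene). It also holds Hox genes of posterior fat depots such as Hoxc9 and Hoxc10. These differed by 0.285 and 0.526 on the log2 scale, with adjusted p-values from limma of 0.623 and 0.622. Both lie near Atf7, at places 9 and 7. Because the list mixes such genes, its rise cannot be assigned to brown depot tissue. With Zic1 and Lhx8 dim, such tissue stays open. The thermogenic list's shift of 0.594 was reached by 1 of 10 splits of the arrays, the real one, with 0.352 as the highest of the others; 10 splits are too few for a share under 0.05. A change of thermogenic genes with the loss of Atf7 stays a hypothesis, and a difference in housing or handling between the mice was not tested.

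For the counts, splits gave the following. At an unadjusted p under 0.05, 3 of 10 splits gave as many genes as the real 1489, with 1903 as the highest other. For lists called, 5 of 10 gave as many as 24, with 28 as the highest other. For genes past the adjusted threshold the real count is 0, so that all 10 of 10 splits reach it by construction (highest other 0), which says nothing about chance. The 10 splits are too few for a share under 0.05.

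Lower lymphocyte genes in KO may come from less lymph node tissue in some dissections, since the inguinal depot holds a lymph node. In KO replicate 3, the array lowest in lymphocyte genes, the lymph node stromal list was -1.21, or -1.534 from the WT mean, while KO replicate 2 lay inside the WT range of the lymphocyte score. Of the 15 stromal genes, 2 are also in other lists. The list's entries include Lta and Ltb, cytokine genes that lymphocytes express. Part of the list can therefore fall with lymphocytes alone. The list also holds Glycam1, the mucin of lymph node venules, which differed by -3.07, and by -1.23 without KO replicate 3. Glycam1 lies near Atf7, at place 28, and its fall rests mostly on that array. The list's level therefore cannot tell lost node tissue from fewer lymphocytes. Fewer lymphocytes and lymph node cells as an effect of the genotype was not tested separately and stays open.

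For genes next to Atf7, flanking DNA from another strain could raise the share over a wide stretch. At places 6 to 50 on each side 1 of 69 genes was changed (1.45%, odds ratio 1.27, 95% interval 0.031 to 7.37, Fisher's exact p = 0.550), and among the 5 nearest on each side 1 of 10, Npff (Fisher's exact p = 0.110), for a local effect of the allele. With so few genes, flanking DNA, a local effect and chance cannot be told apart.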
